A study of Mus musculus with 2 samples.

How the data were processed

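RNA of B cells from mouse lymph nodes was measured on 2 single-colour Agilent arrays, 1 per group. Per the labels, the cells were sorted by flow cytometry on CD19, a surface protein of B cells, and came from female C57BL/6 mice. The tumor-draining group came from nodes of mice that had received 4T1 cells in the mammary gland 2 weeks earlier. 4T1 is a mammary carcinoma line of BALB/c mice, another strain than the one labelled. The normal group came from mice without a tumor. Total RNA was amplified and labelled with Cy3, per the labels' protocols.

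The authors deposited the scanner output of each array, whose values are spot intensity on a linear scale. Per the file headers, Feature Extraction 12.0.3.1 read the images of array design 074809, subtracted background and detrended each array, while the submitters' processing notes name version 10.7 of the same software and limma, with no role given for either. The authors also deposited a series table of log2 values for 56605 probes, with medians of 3.78 for the normal and 3.79 for the tumor-draining array. Its values lie on a log2 scale, not centred per gene and with nearly equal quantiles on both arrays, and the steps that made it are not given in the sources used here. Both arrays lie on the same slide and were read in the same scan, per the file headers, so slide and scan separate no groups.

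Each array holds 62976 spots, of which 59305 carry 56605 gene probes, 3363 are positive and 308 negative controls. Control spots and spots marked as outliers were left out (77 outlier spots on the normal and 115 on the tumor-draining array). No spot was saturated. Processed signals were divided by the array's percentile 75, log2 was taken, and spots of a probe were averaged. A level is therefore a log2 value relative to percentile 75 of its own array. Background subtraction makes dim signals noisy, and a shared scaling point hides any difference in total RNA per cell. A probe counted as measured where at least 1 of its spots was well above background by the scanner software's own mark. A gene's log2 ratio, tumor-draining minus normal, is the mean over its probes measured on both arrays. Where no probe was measured on both, the brightest probe gave a bound: its signal on the bright array against the higher of its own signal and the lowest signal well above background on the dim array, written as "at least".

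Probe names were updated through a table of RefSeq genes of GRCm38.p6, used for names only. By accession 32994 probes were named, by symbol 10223, by synonym 520, and 228 immunoglobulin segment probes by the file's own description. For 12640 probes the file's name was kept, and 19180 probes have no proper gene symbol. Coordinates are those of the array files, on mouse build mm9, and no annotation of that build was used, so exon or UTR placement is not given. Different probes of a gene differed by a median SD of 0.31 in log2 ratio over 6865 genes with several measured probes. In 3030 of these genes probes lay on both sides of 0, and in 23 they were at least 2-fold apart from 0 in opposite directions.

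With 1 array per group there are no replicates, so no test was run and no p-value, SE or SD between samples exists. The number of arrays limits the precision of every value. The only error the arrays give is technical: 284 of the 300 probes spotted 10 times each were well above background, and their log2 ratio had a median SD of 0.23 between spots (percentile 95 of the SDs, 0.53). This covers hybridisation and scanning, not amplification, sorting or animals. The 8 spike-in probes, which detect RNA added in fixed amounts, had a median log2 ratio of -0.23 before scaling (range -0.33 to -0.10) and of -0.85 after it, since the arrays' percentile 75 differed by 0.62 on the log2 scale.

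The groups, the 2-fold threshold, the 46 gene lists, the rule for named genes and the alternatives, except those named as added, were set before the data were examined. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn within 10 bins of mean expression (seed 1), as a description of these 2 arrays. A list stood apart where its median lay in the lowest or highest 2.5% of them, and lists with under 3 members with a value got no percentile. With 45 lists, about 1.12 per side would stand apart if each list were a random draw of genes. Genes of one function can vary together, which random lists do not copy, and lists share members. Neither this count nor a percentile is therefore a measure of chance. Named genes are the 10 highest and 10 lowest ratios among genes with a proper symbol measured on both arrays with all probes on the same side of 0, and the 5 largest bounds each way. They also include, for each list that stood apart, the 3 members furthest in its direction and the 1 furthest in the other, and for other lists up to 2 members each way at 2-fold or more. A set of B cell, T cell and antibody genes is always named: Cd19, Ms4a1, Cd79a, Cd3e, Ighm, Ighd, the IgG and IgA constant genes, Aicda, Bcl6, Prdm1, Xbp1, Mki67, Il10, Cd274, Cxcr4, Ccr7 and Hspa4. The rule takes 177 genes.

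Alternatives were normexp background correction on mean and local background signals (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, median centring, loess on signal (span 0.4, 3 iterations), the authors' series table, no filter on dim probes, only probes measured on both arrays, the brightest probe of a gene, thresholds of 1.5-fold and 4-fold, and random lists not matched on expression. Scaling on the spike-ins, leaving out repeat-bearing probes and leaving out genes of other cell types were added after seeing the data. A probe counted as repeat-bearing where it shares 16 bases in a row with a B1 or B2 consensus or holds a tandem repeat of at least 20 bases. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for this comparison with 21317 genes and the spot noise above. Of 50 genes set 2-fold apart, 66.0% passed the 2-fold threshold, as a value at the threshold falls on either side of it. All 50 at each of 3-, 4- and 8-fold did, and 0 of 21097 unchanged genes did. A simulated list of 20 genes shifted by 0.5 on the log2 scale stood at percentile 100, and 2 of 40 unchanged lists lay at or beyond the limits. The simulation copied the normal array with its background marks and added the same noise to every spot. It holds no bounds, no extra noise of dim probes and no differences in amplification, sorting or animals. It therefore checks the steps and gives no error rate for the real comparison.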

Results

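Gene expression was measured in CD19-sorted lymph node B cells of female mice labelled C57BL/6, on 1 array per group. The normal array came from mice without a tumor. The tumor-draining array came from nodes draining a mammary tumor grown from 4T1 carcinoma cells, a BALB/c line, for 2 weeks. On the normal array 32605 probes (57.6%) were well above background, and on the tumor-draining array 33280 (58.8%). Percentile 75 of the signal was 231 on the normal and 355 on the tumor-draining array, and the median of negative control spots was 21.2 and 23.5. The comparison asks which genes have other RNA levels in B cells of a node that drains a primary tumor.

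Class-switched antibody genes, germinal centre genes and cell division genes had higher signal in B cells of the tumor-draining node. Ighg1, the constant region of IgG1, was 249-fold higher (log2 ratio 7.96), Aicda, the deaminase that starts class switching and somatic hypermutation, 83.2-fold, and Mki67, a marker of cycling cells, 30.4-fold. Of 17 genes of naive follicular B cells 3 were at least 2-fold lower (list median -0.61, but 0.24 when the spike-ins set the scale). On that scale the median gene measured on both arrays stood at 0.71. Lef1, a transcription factor of the Wnt pathway, was 5.04-fold lower and Sell, the homing receptor L-selectin, 2.52-fold. T cell markers were lower beside them (list median -0.34, but 0.51 on the spike-in scale). Which cells carried these transcripts was not tested. Fos, an immediate early transcription factor, was 3.45-fold lower, in a list whose median of -0.76 turned to 0.09 on the scale of the spike-ins. Cd19, the antigen used in the sort, had a log2 ratio of -0.14 and Ms4a1, which encodes CD20, of -0.04, both within the technical SD of 0.23 between spots. On the scale of the spike-ins they read 0.71 and 0.80, near the median gene there.

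Of 22496 genes with a value, 1553 were at least 2-fold higher in the tumor-draining array (1135 measured on both arrays) and 2248 at least 2-fold lower (1357 measured on both), while 18695 lay between. Among genes measured on both, 122 were at least 8-fold higher and 8 at least 8-fold lower. The lowest level well above background was -5.96 on the normal and -6.97 on the tumor-draining array. A gene measured only on the normal array, with its other signal at or below that limit, was therefore at least 2-fold lower by construction. Genes measured only on the tumor-draining array had no such lead, so the counts with bounds favour lower genes, apart from any scaling. The split between higher and lower genes depended on the scaling: 40.9% of the genes past 2-fold were higher here, 68.8% after normexp background correction (713 higher, 323 lower), 61.5% after loess (2242 higher, 1401 lower), 54.6% in the authors' series table (1731 higher, 1440 lower), 52.9% after quantile normalization (1914 higher, 1703 lower), 50.9% after median centring (1880 higher, 1812 lower), and 92.8% when the spike-ins set the scale (7135 higher, 550 lower). The median gene measured on both arrays lay at -0.14 on this scale and at 0.71 when the spike-ins set the scale. Median centring shifts it by 0.13, loess by 0.15 and the spike-ins by 0.85, so each ratio is to be read against that median gene. A shift of all genes alike moves a list's median and leaves its percentile in place, apart from the random draws.

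**Figure D1:**
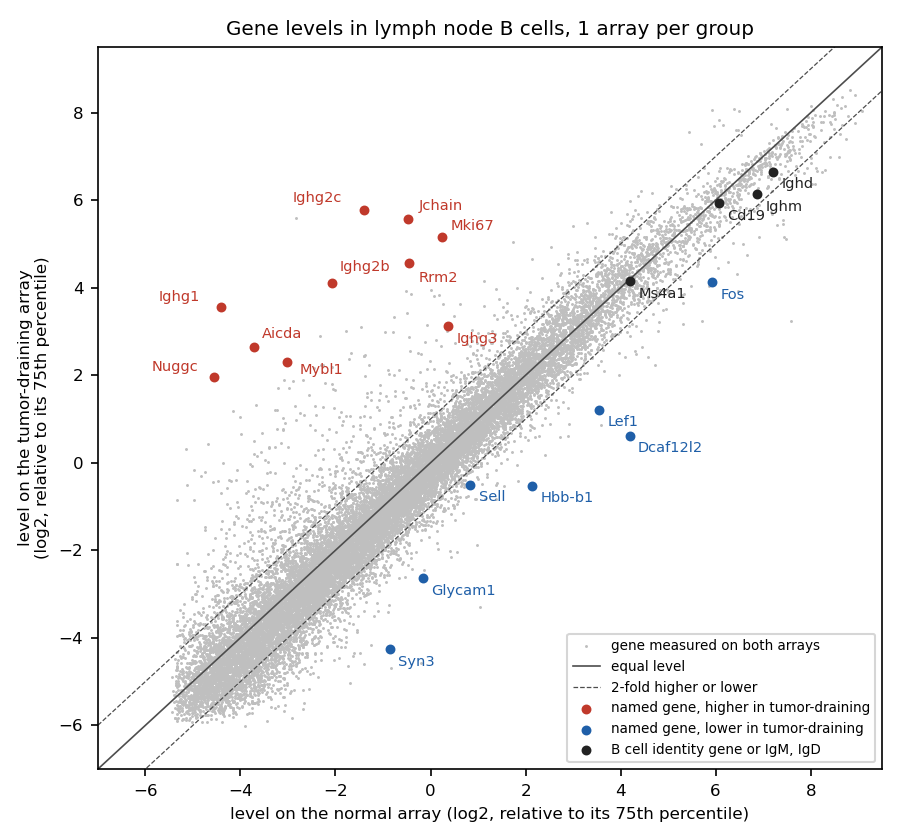
Level of each gene measured on both arrays, normal on the horizontal and tumor-draining on the vertical axis, in log2 units relative to percentile 75 of its own array (1 array per group, 1 point per gene). Ighg1 lies 7.96 above the line of equal level and Aicda 6.38 above it, while Lef1 lies below it at a log2 ratio of -2.33 and Ms4a1 next to it at -0.04.

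The germinal centre list had a median log2 ratio of 2.74, at percentile 100 of random lists, with 13 of 20 members at least 2-fold higher and 0 lower. Nuggc, a germinal centre GTPase gene (probe on chromosome 14, 66267169 to 66267228), was 92.2-fold higher. Aicda (chromosome 6, 122512827 to 122512886) stood at a level of -3.72 on the normal and 2.66 on the tumor-draining array. Mybl1, a transcription factor of germinal centre B cells, was higher by 5.32 on the log2 scale, and S1pr2, the receptor that holds B cells in the germinal centre, 30.1-fold higher. Bcl6, the master regulator of the germinal centre, had a ratio of only 0.53, and Cd38, which mouse germinal centre B cells carry at low level, of -0.13. Neutrophil markers had a median of 0.91 and T cell markers of -0.34 on the same arrays.

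Constant regions of immunoglobulins parted by class. Their list median was 2.74 (percentile 100), with 6 of 11 members at least 2-fold higher and 0 lower. Ighg1 (chromosome 12, 114568594 to 114568653) stood at a level of -4.41 on the normal and 3.56 on the tumor-draining array. Ighg2c, the constant region of IgG2c, was 144-fold higher over 2 of its 3 probes, as the other was not well above background on either array; whether the animals carry IgG2c or its allele IgG2a was not settled. Ighg2b was 72.8-fold higher and Ighg3 6.67-fold. Igha, the IgA constant region, was 6.97-fold higher, although its 2 probes gave log2 ratios of 1.32 and 4.28. Ighe, the IgE constant region, was not well above background on the normal array and at least 597-fold higher on the tumor-draining array. The unswitched classes had ratios of -0.75 for Ighm and -0.56 for Ighd, which turn to 0.10 and 0.29 when the spike-ins set the scale. Variable region segments had a median of 0.15 (percentile 100), with 12 of 186 at least 2-fold higher and 5 lower. Among them Igkv5-37 was at least 27.3-fold higher and Igkv7-33 6.17-fold higher. The class switch and hypermutation list as a whole had a median of 0.14 (percentile 92.9): Aicda and Exo1, a mismatch repair exonuclease that was 7.18-fold higher, were among its 4 of 19 members past 2-fold, and 0 were lower.

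All 30 members of the mitosis list were at least 2-fold higher, with a median of 4.08 (percentile 100). Ube2c, a ubiquitin-conjugating enzyme of the anaphase, was 37.0-fold higher, Bub1, a spindle checkpoint kinase, 33.0-fold, and Kif11, a spindle motor, at least 41.5-fold. Cenpa, the centromeric histone, was the member nearest to 0 at 2.19-fold. In the DNA replication list 25 of 29 members were at least 2-fold higher and 0 lower (median 1.91, percentile 100). Rrm2, a subunit of ribonucleotide reductase (chromosome 12, 25398824 to 25398883), was 32.5-fold higher, Mcm10, a replication initiation factor, 16.1-fold, and Dhfr, dihydrofolate reductase, 13.4-fold, whereas Ung, the uracil glycosylase, had a ratio of -0.01 on its only probe, which holds a tandem repeat. Replication-dependent histones had a median of 1.48 (percentile 100), with 35 of 53 at least 2-fold higher and 1 lower. H1f5, a linker histone, was 21.9-fold higher and H1f6, the testis linker histone, at least 4.58-fold lower. Outside these lists, Espl1, the protease separase, was 40.4-fold higher, Pipox, a peroxisomal oxidase, 35.1-fold, Aunip, an Aurora A partner, at least 44.1-fold, Kif18b, a kinesin, at least 34.5-fold, and Gstt1, a glutathione transferase, at least 29.3-fold. Markers of macrophages (median 0.55) and of mast cells (0.93) were also higher in this array.

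**Figure D2:**
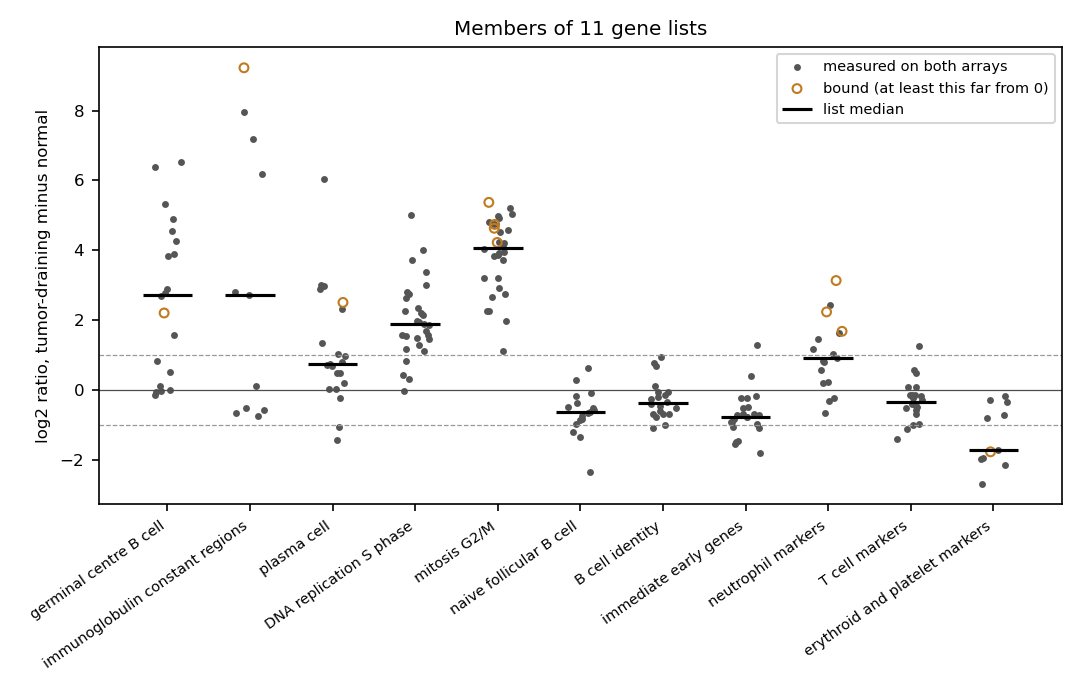
Log2 ratio (tumor-draining minus normal) of each member of 11 gene lists; filled points are genes measured on both arrays, open points are bounds, the bar is the list median, and dashed lines mark 2-fold. All 30 mitosis members lie above 1, while the erythroid and platelet list has a median of -1.70. With the spike-ins setting the scale the medians of the naive follicular (0.24), B cell identity (0.49), immediate early (0.09) and T cell (0.51) lists lie above 0. They stay below the median gene measured on both arrays, which lies at 0.71 on that scale.

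Plasma cell genes were higher on the median (0.75, percentile 100), with 8 of 21 members at least 2-fold higher and 2 lower. Jchain, the joining chain of polymeric IgM and IgA (chromosome 5, 88949919 to 88949978), was 66.3-fold higher, and Derl3, a gene of endoplasmic reticulum degradation, 7.94-fold. Slpi, a protease inhibitor, was 8.03-fold higher with probes between 0.34 and 5.68. The regulators gave smaller values: Xbp1 was 2.57-fold higher, Prdm1, which encodes Blimp-1, had a ratio of 0.75, and Irf4 was 2.06-fold lower. Ly6d was 2.68-fold lower. Sdc1, a member of this list given here outside the naming rule, had a ratio of -0.23 over 3 probes. Whether plasma cells carried the Jchain transcripts was not tested. The unfolded protein response list had a median of 0.34 (percentile 99.8), with 3 of 25 members at least 2-fold higher and 0 lower. Sdf2l1, an endoplasmic reticulum chaperone component, was 3.43-fold higher and Edem1, of glycoprotein degradation, 2.29-fold, while Ddit3, the stress factor CHOP, had a ratio of -0.84. Glycolysis genes had a median of 0.48 (percentile 99.96), 3 of 19 at least 2-fold higher and 2 lower, with Slc16a3, a lactate exporter, 3.59-fold and Tpi1, triosephosphate isomerase, 2.19-fold higher and Pfkm, muscle phosphofructokinase, 2.63-fold lower. Gapdh was 2.08-fold higher over 7 probes with log2 ratios from 0.19 to 1.44. The 4 Tpi1 probes ran from -0.02 to 1.65, and Slc16a3 rested on 1 of 2 probes. Oxidative phosphorylation genes had a median of 0.37 (percentile 99.7), 2 of 26 at least 2-fold higher and 0 lower, with Cox6c, a cytochrome oxidase subunit, 3.29-fold and Uqcrc2, of complex III, 2.20-fold higher and Ndufs3, of complex I, at -0.39. Cytosolic ribosomal proteins had a median of -0.21 (percentile 0.06), 2 of 81 at least 2-fold lower and 1 higher, but a median of 0.64 when the spike-ins set the scale. Rpl13a was 3.64-fold lower and Rps27l, a p53-responsive paralog, 2.34-fold higher. Percentiles of this list were 32.2 after quantile normalization, 17.1 in the authors' series table and 19.0 against random lists not matched on expression, so its place at the low end depends on these choices. Dendritic cell markers (median 0.43) were higher beside these groups.

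Genes of naive follicular B cells had a median of -0.61 (percentile 0), with 3 of 17 members at least 2-fold lower and 0 higher, and a median of 0.24 when the spike-ins set the scale. Besides Lef1 (chromosome 3, 130926200 to 130926259, 1 of 3 probes measured on both arrays) and Sell, Satb1, a chromatin organiser, was 2.30-fold lower. Ccr7, the receptor that guides lymphocytes into the node, had a ratio of -0.96, and Gpr183, which guides B cells within follicles, of 0.65. B cell identity genes had a median of -0.36 (percentile 0.16, but 7.65 against random lists not matched on expression, with a median of 0.49 on the spike-in scale), with 1 of 20 at least 2-fold lower and 0 higher. Cd79b, a signalling chain of the B cell receptor, was 2.13-fold lower, and Bank1, an adaptor, had a ratio of -0.77. Cd24a had a ratio of 0.95 and Cd79a, the partner of Cd79b, of -0.25. The B cell receptor signalling list had a median of -0.25 (percentile 1.08, but 19.6 against unmatched random lists, with a median of 0.60 on the spike-in scale), with 1 of 28 at least 2-fold lower and 0 higher. Blk, a kinase of that pathway, stood at a level of 0.91 on the normal and -0.09 on the tumor-draining array. Cd72, an inhibitory coreceptor, had a ratio of -0.67 and Cd81, of the Cd19 complex, of 0.26. Genes of antigen presentation on MHC class II had a median of -0.42 (percentile 0.31, with a median of 0.43 on the spike-in scale), with 2 of 14 at least 2-fold lower and 0 higher. Marchf1, a ubiquitin ligase that removes MHC class II from the surface, was 2.61-fold lower and H2-Eb1, an MHC class II chain, 2.54-fold. H2-Ab1 had a ratio of -0.98 with probes from -2.21 to -0.09, and H2-DMa, the peptide exchange factor, of 0.03. This list missed the limit after quantile normalization (4.19), in the series table (3.38) and against unmatched random lists (6.67). T cell markers, which a B cell sort should exclude, moved with these lists at a median of -0.34. Whether B or T cells carried Lef1, Sell and Satb1 was not tested.

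Immediate early genes, which respond within minutes to receptor signals and to cell handling, had a median of -0.76 (percentile 0, with a median of 0.09 on the spike-in scale), with 6 of 23 members at least 2-fold lower and 1 higher. Fos (chromosome 12, 86818118 to 86818177) was 3.45-fold lower, Fosb 2.92-fold and Junb 2.76-fold, while Ier3 was 2.46-fold higher. Interferon-stimulated genes, the antiviral programme of type I interferon, had a median of -0.44 (percentile 0.04, with a median of 0.41 on the spike-in scale), with 4 of 30 at least 2-fold lower and 2 higher. Rsad2, the antiviral enzyme viperin, was 3.86-fold lower, Ifit3 2.92-fold and Ifit1 2.67-fold, and Oasl2 was at least 7.84-fold higher. The interferon-gamma list went the other way, with a median of 0.66 (percentile 100), 5 of 24 at least 2-fold higher and 0 lower. Ido1, which degrades tryptophan, was at least 27.7-fold higher, and the chemokine genes Cxcl9 and Cxcl10 were 4.12-fold and 3.51-fold higher, while Irf1 had a ratio of -0.32. Macrophage markers had a median of 0.55 beside them.

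Chemokines had a median of 0.80 (percentile 100), with 10 of 22 at least 2-fold higher and 0 lower. Ccl24, an eosinophil attractant, was at least 9.39-fold higher and Ccl3, a ligand of Ccr5, 6.56-fold, and Ccl21a, made by stroma, had a ratio of -0.90. Regulatory B cell genes had a median of 0.31 (percentile 99.6), 9 of 19 at least 2-fold higher and 1 lower, but a median of -0.04 and percentile 93.6 after normexp and percentile 92.4 with only probes measured on both arrays. Ido1, also in the interferon-gamma list, was at least 27.7-fold higher. Nt5e, the ectoenzyme CD73, was higher by 3.81 on the log2 scale, and Havcr1, which encodes TIM-1, was 4.81-fold higher. Il10, the cytokine by which regulatory B cells are defined, was at least 2.30-fold higher from a level not well above background on the normal array. Il12a, a subunit of IL-12 and IL-35, was 2.49-fold lower. Costimulation and checkpoint genes had a median of 0.53 (percentile 99.99), 10 of 25 at least 2-fold higher and 0 lower, but a median of -0.04 after normexp and percentile 81.5 (median 0.03) with the brightest probe of a gene. Cd70, a ligand of CD27, was at least 5.06-fold and the inhibitory receptor Tigit at least 4.74-fold higher, while Cd274, which encodes PD-L1, had a ratio of -0.27 and Lgals9, galectin-9, of -0.73. Cytokines had a median of 0.17 (percentile 98.4), 5 of 26 at least 2-fold higher and 2 lower, but -0.35 at percentile 32.1 after normexp and -0.20 at percentile 47.6 with only probes measured on both arrays. Il4, the cytokine of switching to IgG1 and IgE, was at least 18.1-fold higher, Tnfsf11, which encodes RANKL, at least 4.59-fold and Il1b 4.26-fold. Neutrophil (median 0.91) and NK cell markers (0.48) were higher on the same array.

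Markers of other cell types did not share a direction. After normexp the medians of the neutrophil (0.00), mast cell (0.21), macrophage (0.16) and dendritic cell (0.20) lists were near 0, although all 4 lists stayed in the top 2.5%. Neutrophil markers had a median of 0.91 (percentile 99.99), 8 of 17 at least 2-fold higher and 0 lower: Ltf, lactoferrin, was at least 8.81-fold and S100a9, a calcium-binding alarmin, 5.47-fold higher, and Csf3r, the G-CSF receptor, had a ratio of -0.66 from a probe that holds a B1 repeat. Mast cell and basophil markers had a median of 0.93 (percentile 99.99), 6 of 12 at least 2-fold higher and 0 lower, with the basophil protease Mcpt8 6.04-fold and the mast cell protease Cpa3 3.83-fold higher and Ms4a2, a chain of the IgE receptor, at -0.77. Macrophage and monocyte markers had a median of 0.55 (percentile 100), 8 of 19 at least 2-fold higher and 1 lower: Fcgr1 was at least 3.64-fold and Mafb 3.38-fold higher, and Marco, a scavenger receptor, 2.20-fold lower. Dendritic cell markers had a median of 0.43 (percentile 99.9), 4 of 17 at least 2-fold higher and 0 lower, with Batf3 3.28-fold and Clec10a 3.14-fold higher and Snx22 at -0.65. NK cell markers had a median of 0.48 (percentile 99.9), 2 of 16 at least 2-fold higher and 1 lower, but -0.13 at percentile 86.2 after normexp and percentile 89.8 with no filter on dim probes. Gzmb, granzyme B, which is also in the regulatory B cell list, was 4.79-fold higher. Gzma, granzyme A, was 2.01-fold higher and Cd244a, with a B1 repeat among its 3 probes, 2.03-fold lower. T cell markers had a median of -0.34 (percentile 1.21, but 3.17 after normexp and 8.85 against unmatched random lists, with a median of 0.51 on the spike-in scale), 2 of 22 at least 2-fold lower and 1 higher: Itk was 2.61-fold and Ubash3a 2.15-fold lower, Cd3e had a ratio of -0.69 (0.16 on the spike-in scale), and Icos, a receptor of follicular helper T cells, was 2.42-fold higher. Lymph node stroma markers had a median of -0.91 (percentile 0.07, but 32.1 with no filter on dim probes, where the median was -0.45), 6 of 14 at least 2-fold lower and 1 higher, with Col1a1 4.29-fold and Col3a1 3.80-fold lower, Col6a1 at least 3.84-fold lower and Cxcl13, the follicular chemokine, 3.30-fold higher. Erythroid and platelet markers had a median of -1.70 (percentile 0), 6 of 11 at least 2-fold lower and 0 higher, with Hbb-b1, a beta globin, 6.35-fold and Alas2, of heme synthesis, 3.89-fold lower and Car2, a carbonic anhydrase, at -0.17. Endothelial markers (0.10, percentile 89.7) did not stand apart, with Glycam1, of high endothelial venules, 5.57-fold lower and Cdh5 at least 3.12-fold higher. Epithelial and carcinoma markers did not either (-0.12, percentile 74.4), with Krt5, a basal keratin, at least 4.38-fold lower and Wfdc2 at least 3.26-fold higher. Of 6 Y-linked genes 1 had a value and no percentile was given.

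**Figure D3:**
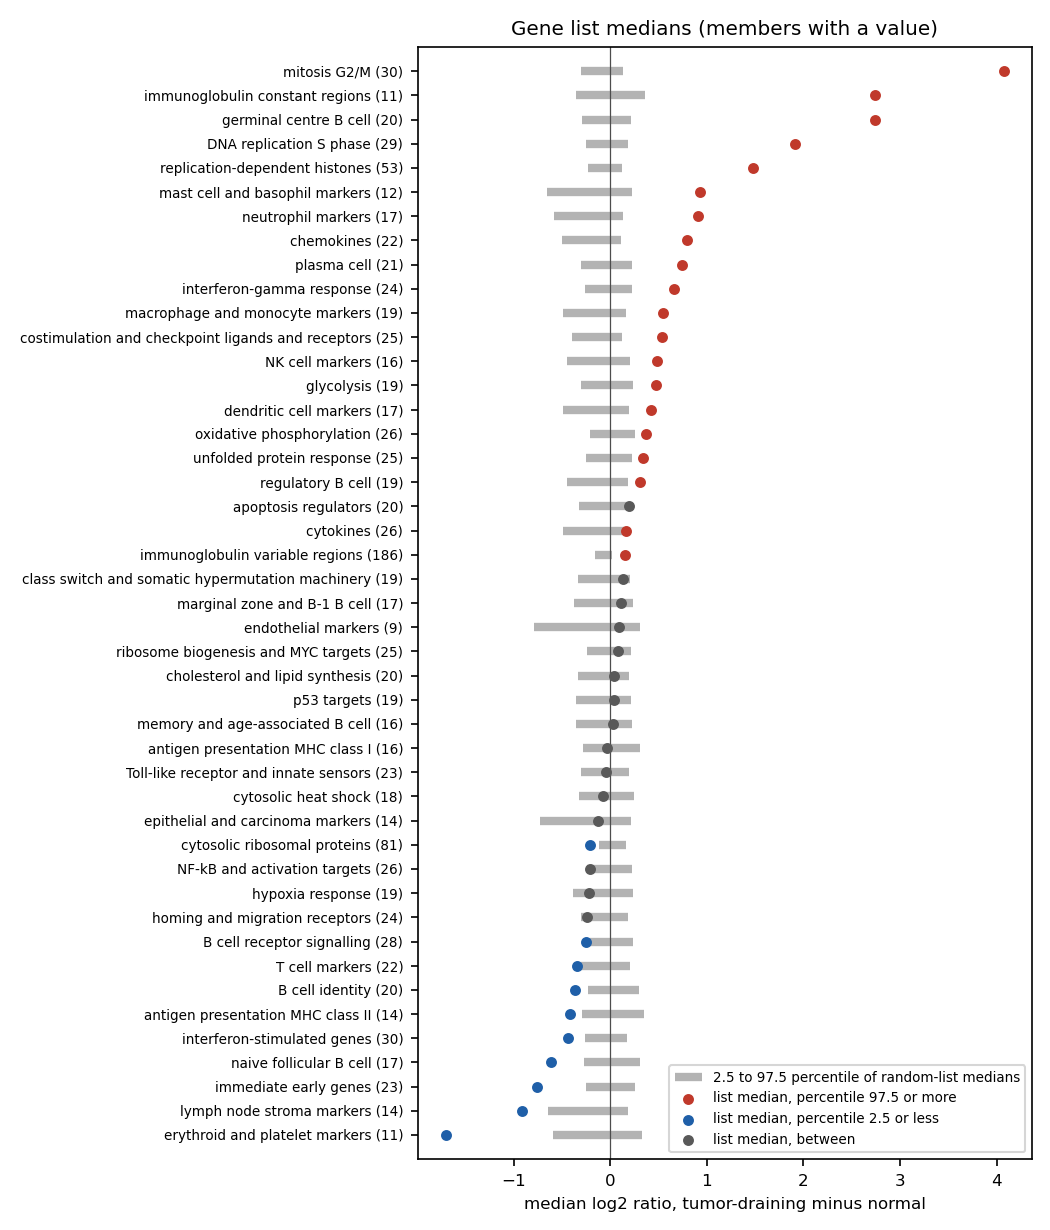
Median log2 ratio (tumor-draining minus normal) of 45 gene lists, with the number of members that have a value in brackets; grey bars leave out the lowest and highest 2.5% of the medians of 10000 random lists matched on expression. On these arrays 20 lists lie at or above the upper limit, 10 at or below the lower and 15 between, and the lower medians of the B cell identity, naive follicular, immediate early, interferon-stimulated, MHC class II, B cell receptor, ribosomal protein and T cell lists lie above 0 with the spike-ins setting the scale. They stay below the median gene measured on both arrays, which lies at 0.71 on that scale.

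Among the lists that did not stand apart, marginal zone and B-1 genes had a median of 0.11 (percentile 88.7), with S1pr3, a sphingosine-phosphate receptor, 3.39-fold and Ctla4 2.97-fold higher and Bhlhe41, a B-1 transcription factor, 2.82-fold lower. Memory and age-associated genes (0.03, percentile 76.7) held Cxcr3, the receptor of Cxcl9 and Cxcl10, 2.96-fold higher. Homing receptors (-0.24, percentile 7.43) held 3 members at least 2-fold higher and 3 lower: S1pr2 30.1-fold and Cxcr3 2.96-fold higher, Ackr3, a scavenger of Cxcl12, 5.17-fold and Sell 2.52-fold lower, and Cxcr4 at -0.07. NF-kB targets (-0.21, percentile 4.52) held Traf1 2.75-fold higher and Birc3 2.23-fold lower. Toll-like receptor genes had a median of -0.04 (percentile 55.9), with Cd14 2.36-fold higher, and MHC class I genes of -0.03 (percentile 41.3). Hypoxia genes (-0.22, percentile 19.8) held 5 members at least 2-fold lower and 1 higher, with Adm, adrenomedullin, 2.94-fold and Ddit4 2.42-fold lower and Egln3, a prolyl hydroxylase, at least 2.17-fold higher. Heat shock genes (-0.07, percentile 44.9) held Hspa1b 3.30-fold lower and Hspa4 at -0.03. Apoptosis regulators (0.19, percentile 97.1) held Casp3, an executioner caspase, 4.14-fold and Bak1 2.97-fold higher, and Bmf 2.35-fold lower. Ribosome biogenesis genes (0.08, percentile 79.9) held Nhp2 3.01-fold higher, p53 targets (0.04, percentile 78.3) Gtse1, which is made in G2, 8.23-fold higher, and cholesterol synthesis genes (0.04, percentile 82.7) Idi1 4.88-fold higher. Neutrophil and mast cell markers moved with the higher members named here, by medians of 0.91 and 0.93.

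Several of the lowest ratios among single genes rested on 1 of several probes or on probes with repeats. As classes, chosen after their values were seen, probes with a B1 repeat had a median ratio of -0.57 and those with a B2 repeat of -0.66. Dcaf12l2 was 11.9-fold lower on a probe that holds a tandem repeat, Syn3, a synapsin, 10.6-fold on 1 of 6 probes, Sez6l 9.19-fold on 1 of 3 and Mpp3 7.59-fold on 1 of 5. Thsd4 was 7.30-fold lower on a probe with a B2 repeat. Cldn14, a claudin, was 6.64-fold lower, Apol8 6.07-fold and Krtap16-3, a hair keratin-associated gene, 5.55-fold. Bounds reached at least 23.9-fold lower for Chst9, a sulfotransferase, 15.2-fold for Gli1, a Hedgehog transcription factor, 15.0-fold for Soga3, a log2 ratio of -3.59 for Vmn2r29, a vomeronasal receptor gene, and 11.9-fold for Slc26a1, an anion exchanger. With 1 array per group these differences have no replicate check and describe these 2 arrays.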

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

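The tests of explanations in this part, spike-in scaling, leaving out repeat-bearing probes and the genes Krt18, S100a8 and Ngp were chosen after the result was seen; the lists, their percentiles and the other settings were fixed before. With 1 array per group, no sample has others of its group to be compared with and no difference between groups' effects exists to test.

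Germinal centre, mitosis, S phase, histone and immunoglobulin constant genes were higher in the tumor-draining array, with list medians from 1.48 to 4.08. A trend with signal or the choice of scaling is argued against as the whole cause: over 6 scaling alternatives the lowest median of the 5 lists was 1.29 (histones, after normexp), above 2-fold. Median centring and spike-in scaling raise all genes alike, by 0.13 and 0.85, and could not have lowered these medians. The argument therefore rests on the other alternatives. Carcinoma cells among the sorted cells are argued against as the whole cause, as far as 4T1 cells make these markers: the epithelial and carcinoma list, whose genes would have to move about as far, had a median of -0.12 (SD 0.895 across 14 members), below 1.48 by more than that SD. These lists were fixed by function, and of the germinal centre list 1 member, Ung, is also a replication gene. A small share of carcinoma cells (Wfdc2 was at least 3.26-fold higher and Krt18 higher by 0.68), a germinal centre reaction in the draining node, differences between animals, sites of the nodes and handling all stay open and untested, because they vary with the group. A mismatch of strain between tumor and animals stays open too, as the labels give C57BL/6 and 4T1 is a line of BALB/c mice. The labelled strain is itself uncertain: H2-Ea, whose transcript C57BL/6 mice lack, was well above background on both arrays (levels 3.83 and 2.91), though cross-hybridisation was not tested.

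Neutrophil, macrophage, dendritic, NK and mast cell markers were higher in the tumor-draining array while T cell, stroma and erythroid markers were lower. If the mix of other cells stayed the same, a lower share of B cells would raise every other cell type alike. Yet 3 of the 10 lists of other cell types lay at or below percentile 2.5 and 5 in the top 2.5%. Over the 9 settings that can move a percentile only 1 of the low lists, erythroid markers, kept its side (percentiles up to 2.32, medians -1.70 to -0.61). Of the high ones 4 did, all but NK cells. The argument against a lower share with the same mix therefore rests on erythroid markers. A lower share with another mix of other cells stays open, as these lists cannot test it. B cell identity genes had a median of -0.36, with 16 of 20 members below 0 and 4 above. Their percentile was 0.16, but 7.65 against random lists not matched on expression. Their median was 0.49 on the spike-in scale, where the median gene measured on both arrays stood at 0.71. Myeloid and mast cells that passed the CD19 sort could raise their markers: 22 of 48 members of the neutrophil, macrophage and mast cell lists (45.8%) were at least 2-fold higher, between the limits of 80% and 20% set for and against this. Carry-over and expression in B cells cannot be told apart here, since the arrays hold no measure of single cells and neutrophil genes part, with S100a9 higher by 2.45 and S100a8 by 1.63 but Ngp at -0.30.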

How the results depend on the processing

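The tests with spike-in scaling, without repeat-bearing probes and without genes of other cell types were chosen after seeing the data. Of 30 lists that stood apart, 20 kept their side (16 high, 4 low) in the 9 settings that can move a percentile, as median centring and spike-in scaling shift all genes alike. Over all 11 settings medians were 2.46 to 3.59 for germinal centre, 2.87 to 4.93 for mitosis and -0.86 to 0.09 for immediate early genes, and 3 of the 4 low lists had a median above 0 with spike-in scaling. That scaling puts the median gene measured on both arrays at 0.71. Counts of genes at least 2-fold higher and lower (1553 and 2248) became 713 and 323 under normexp, 7135 and 550 with spike-in scaling, 3156 and 5086 at 1.5-fold and 452 and 435 at 4-fold. The lower count became 1401 under loess, 1440 in the series table, 1357 with only probes measured on both arrays, where bounds are left out by construction, and 5159 with no filter on dim probes. Without the 179 genes of the other cell type lists the counts were 1521 and 2229, and without repeat-bearing probes 1556 and 2225. Under normexp 84 of 142 named genes past 2-fold stayed past it, 53 did not and 5 had no value. With spike-in scaling 115 stayed past it and 27 did not. Sqle turned to -0.19 with no filter. List percentiles that crossed a limit were, under normexp, regulatory B cell 93.6, NF-kB 0.28, cytokines 32.1 (median -0.35, the other direction), homing 1.72, T cell 3.17 and NK cell 86.2. With only probes measured on both arrays they were regulatory B cell 92.4, NF-kB 2.26 and cytokines 47.6 (median -0.20, the other direction). After quantile normalization MHC class II stood at 4.19 and ribosomal proteins at 32.2, in the series table at 3.38 and 17.1, and under loess class switch genes at 97.53. Against random lists not matched on expression, B cell identity stood at 7.65, MHC class II at 6.67, B cell receptor signalling at 19.6, ribosomal proteins at 19.0, T cell at 8.85 and apoptosis at 97.7. With the brightest probe of a gene NF-kB stood at 0.51 and costimulation at 81.5, and with no filter NK cell at 89.8 and stroma at 32.1. Except for the bounds and thresholds, the cause was not tested. Leaving out saturated spots was not run, as no spot was saturated. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes, whose ratios are bounds.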

Other observations

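The tests of explanations, the probe classes and single probes, and 11 gene lists with the members named, of which 7 lists lay in the top 2.5%, were chosen after the data were seen; the T cell and cytosolic ribosomal protein lists were fixed before.

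Genes of follicular helper T cells had a median log2 ratio of 1.05 (percentile 100, and at least 99.9 over normexp, quantile, loess and series table values), with 6 of 12 members at least 2-fold higher and 0 lower, although T cell markers in general had a median of -0.34. Il4 was higher by at least 4.18, Ascl2, a transcription factor of these cells, by at least 3.12, Tox2 by 2.06 and Pdcd1, which encodes PD-1, by 1.78, while Il21, their leading cytokine, had a ratio of -0.41. Of these members 7 are also in lists fixed earlier, and germinal centre B cells share some of them. Fanconi anaemia and homologous recombination genes, which repair broken and crosslinked DNA, had a median of 1.60 (percentile 100), 10 of 17 at least 2-fold higher and 0 lower: Brip1, a helicase, was higher by at least 3.72, Rad54b by 3.07 and Rad54l by 2.79. Kinesins had a median of 0.35 (percentile 99.99), 10 of 34 at least 2-fold higher and 1 lower, with Kif4 at 4.62, Kif15 at 4.48, Kif20b at 0.63, Kif5b at 0.33 and Kif2a at -0.18. Of the kinesins 4 are also in lists fixed earlier.

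Mitochondrial ribosomal proteins had a median of 0.42 (percentile 100), 6 of 78 at least 2-fold higher and 0 lower, against -0.21 for cytosolic ribosomal proteins. The low place of the cytosolic list depended on the processing. Its percentile was 32.2 after quantile normalization, 17.1 in the authors' series table and 19.0 against random lists not matched on expression. Proteasome subunits had a median of 0.29 (percentile 99.7) with 0 of 38 past 2-fold, and 3 of them are also in lists fixed earlier. Oxidative stress genes had a median of 0.46 (percentile 99.9), 5 of 16 at least 2-fold higher and 0 lower: Txn1, thioredoxin, was higher by 1.78 and Srxn1, sulfiredoxin, by 2.10. Genes of KRAB repression and DNA methylation had a median of 0.75 (percentile 99.95) over 9 members, 4 at least 2-fold higher and 0 lower. Uhrf1, also in the S phase list, stood at 3.01, Hells, a remodeler, at 2.22 and Cbx5 at 1.62. The KRAB corepressor genes Trim28 and Setdb1 stood at -0.22 and -0.23. Of the methyltransferase genes Dnmt1 stood at 0.75, Dnmt3a at -0.53 and Dnmt3b at -0.68. Nucleoporins (0.21, percentile 96.7) lay between percentiles 95.7 and 99.0 over normexp, quantile, loess and series table values, so their call depends on the processing. Aminoacyl-tRNA synthetases (0.08, percentile 83.9), 317 zinc finger genes (-0.15, percentile 23.9) and glycosyltransferases (-0.03, percentile 59.7) did not stand apart.

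Probes that carry repeats read lower in the tumor-draining array: 49 with a B1 element had a median of -0.57 and 63 with a B2 element of -0.66, where other probes of the same signal had 0.05, and 138 with a tandem repeat had -0.27. Probes for intergenic or lincRNA loci, 2086 of them, had a median of -0.37, where other probes of the same signal had -0.20, with 263 at least 2-fold lower and 65 higher. The 28S ribosomal RNA probe, Rn28s1, had a ratio of -2.28. Of 1357 genes measured on both arrays and at least 2-fold lower, 34 had a repeat-bearing probe, against 2 of 1135 higher ones. The probe of Gm5820 on chromosome 18 (39130867 to 39130926) was not well above background on the normal array and at a level of 6.02 on the tumor-draining array, at least 4027-fold higher, and was chosen after its value was seen. Of 15 probes for Y-linked genes 1 was well above background on either array, a Kdm5d probe at -2.75 and -3.51, and Xist stood at 0.12 on the normal and -0.14 on the tumor-draining array.

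The labels give C57BL/6 as the strain. H2-Ea, whose transcript C57BL/6 mice lack through a promoter deletion, was well above background on both arrays, at 3.83 on the normal and 2.91 on the tumor-draining array. This value suggests, as a hypothesis, that the animals carried alleles of another strain than C57BL/6 at H2, and 4T1 is a line of BALB/c mice, but cross-hybridisation was not tested. Alleles of another strain at Igh stay open, since the probes point both ways: one described as a BALB/c heavy chain stood at -2.83 on the normal and 5.59 on the tumor-draining array, and 2 of 3 Ighg2c probes were well above background, at -1.11 and -1.70 on the normal and 5.89 and 5.65 on the tumor-draining array, while the other (chromosome 12, 114525673 to 114525732) was not on either. Different H2 alleles in the normal and the tumor-bearing animals stay open too: the ratios of 7 probes for MHC class II chains (H2-Ea, H2-Aa, H2-Eb1 and H2-Ab1) lay 2.13 apart, from -2.21 to -0.09 within H2-Ab1, and any haplotypes that express H2-Ea would read alike.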
